A study of Macaca fascicularis with 12 samples.

How the data were processed

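Gene expression was measured in brain tissue of 3 adult male cynomolgus macaques. Per the labels' protocols, each animal received 4 intrastriatal injections of the baculovirus BV-HSVtk in the left hemisphere, 10 µL with 1e8 particles per injection, and a mock preparation at matching coordinates on the right. The mock preparation was virus-free insect cell medium (Sf9) taken through the same purification. Pieces of about 100 mg were taken 2 days later, 2 pieces per hemisphere, and each piece was hybridised to 1 array. This gives 12 arrays, 6 from BV-injected and 6 from mock-injected tissue. Replicate numbers follow the titles: numbers 1 and 2 are animal 1, 3 and 4 are animal 2, and 5 and 6 are animal 3, with odd numbers for piece 1 and even numbers for piece 2. Virus was always in the left hemisphere, so treatment and hemisphere cannot be told apart.

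Total RNA was extracted with Trizol and cleaned on a column, and 5 µg was labelled, per the labels' protocols. These name labelling kits of 2 makers without saying which arrays got which. The deposited values are linear probe set intensities, 1 column per array, and the submitters' processing notes name GCOS 1.4.0.036 as software. The summary algorithm, the scaling target and any filter are not given in the sources used here. No detection calls were used. The piece 2 arrays had a mean of 100.01 after trimming 2% of values at each end, alike on all 6, and medians between 25.4 and 32.7. The piece 1 arrays had trimmed means between 142 and 189 and medians between 50.2 and 62.8. The piece number is therefore a technical array set as well, balanced over animals and treatment.

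Because the array medians differed, the rule fixed beforehand called for quantile normalization of the 12 arrays. Values were then taken as log2(signal + 3.49), the pseudocount being the 10th percentile of all deposited intensities, so folds of dim probe sets are understated. Control probe sets (99) were left out. Of the other 52766 probe sets, the 31660 with a mean log2 value at or above the 40th percentile (4.95) were tested. Gene symbols came from the platform annotation of a rhesus macaque array: 24969 probe sets had 1 symbol, 361 had several and were left unnamed, and 27535 had none listed. Of the 14133 distinct symbols, 12584 also occur in a table of Macaca fascicularis genes. Cynomolgus RNA on probes designed for rhesus can bind less well where the species differ, and symbols may be outdated.

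The pieces of each hemisphere were averaged on the log2 scale, which left 3 BV and 3 mock values. These were fitted in limma 3.58.1 under R 4.3.3 with animal as a block and treatment as a term, with eBayes and a trend, 2 residual degrees of freedom and Benjamini-Hochberg adjustment at 0.05, two-sided. The block follows from the protocol, in which each animal carries both treatments. The deviations of both hemispheres of an animal from their group means correlated at r = 0.622, 0.156 and 0.361 over probe sets for animals 1, 2 and 3. Correlations and counts over genes describe these arrays, and genes are not independent replicates. A limma F test of the animal by treatment interaction used the 12 single arrays.

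There were 33 gene lists fixed beforehand, of which 31 had at least 5 measured members. Interferon ligands and receptors, and haemoglobin and red cell genes, each had 2 measured members and were not tested. Each gene was represented by its brightest probe set. Some genes are on several lists. The sensor and apoptosis lists share members with the interferon-stimulated list, and the neutrophil list with the reactive astrocyte list. Calls of such lists are not independent. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01 and adjusted over the lists, and again with an estimated correlation and with fry. The genes named in the text were set by rule: the 10 raised and 10 lowered genes of largest fold that passed and moved alike in 3 animals; up to 3 passing members of each list or otherwise the 2 of largest fold; the 5 of smallest p in a direction with fewer than 5 passing genes; and a panel of genes fixed beforehand. From the panel, IFNB1 and TNF fell below the intensity filter, and SNAP25 had no probe set of its own symbol. Genes named outside the rule are said to be so.

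On simulated data with the real means and spreads, but with independent noise on each array, the fit over 31660 probe sets recovered 4.55% of genes changed by 1 log2 unit, 70.1% of those changed by 2 and 98.5% of those changed by 4. It made 2 false calls among 31460 unchanged probe sets. A simulated list shifted by 0.8 was called and 0 of 30 unchanged lists were. These lists were random genes simulated without correlation between genes, so they cannot show how often real lists are called by chance. The interferon-stimulated list had an estimated inter-gene correlation of 0.59. The number of arrays and animals limits the precision.

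Alternatives fixed before the data were examined covered the pseudocount, the filter, the normalization, the variance trend, the block, the use of single arrays, a 2-fold minimum, each animal and each array left out, and the list tests. Added after seeing the data were fits within each array set, normalization within each set, a term for piece number, and a covariate made of thalamic marker genes, either all those measured or only the 5 not seen beforehand. That marker list held 16 genes, of which TCF7L2, SHOX2 and NTNG1 had been seen in the data before it was written. Figures were drawn with matplotlib from the values given.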

Results

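Intrastriatal injection of a baculovirus vector was compared with mock injection in 3 cynomolgus macaques, 2 days after injection, to ask which transcripts differ in the injected brain. Baculoviruses infect insect cells and are used as vectors that enter mammalian cells without replicating. BV-HSVtk is named for herpes simplex virus thymidine kinase. There were 12 arrays from 6 hemispheres, 6 arrays per group, with 2 tissue pieces per hemisphere. All folds below are BV minus mock on the log2 scale, n = 3 animals, with the standard error of the limma fit.

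BV-injected tissue had more transcript of 7 genes, as the array annotation names them, of which ISG15, MX1, IFI27, IFIT3 and IFITM1 are induced by interferon. ISG15, a ubiquitin-like protein that is attached to other proteins during the interferon response, rose most, by 3.56 ± 0.13 or 11.8-fold (adjusted p = 0.00539). MX1, a GTPase that blocks many viruses, rose by 3.04 ± 0.19 (adjusted p = 0.0256), IFI27 by 2.55 ± 0.16 and IFIT3, one of the tetratricopeptide antiviral proteins, by 2.13 ± 0.14. Also raised were 3 probe sets named TTLL6, a gene for a tubulin-modifying enzyme, the brightest by 2.64 ± 0.18, and RPL24, a protein of the large ribosomal subunit, by 1.46 ± 0.09. A probe set of IFITM1, a membrane protein that hinders virus entry, rose by 1.45 ± 0.10, while its brighter probe set had a fold of 1.24 ± 0.12 that did not pass (adjusted p = 0.117). Whether the probe sets named TTLL6 and RPL24 measure those genes could not be checked, as probe sequences were not given.

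**Figure D1:**
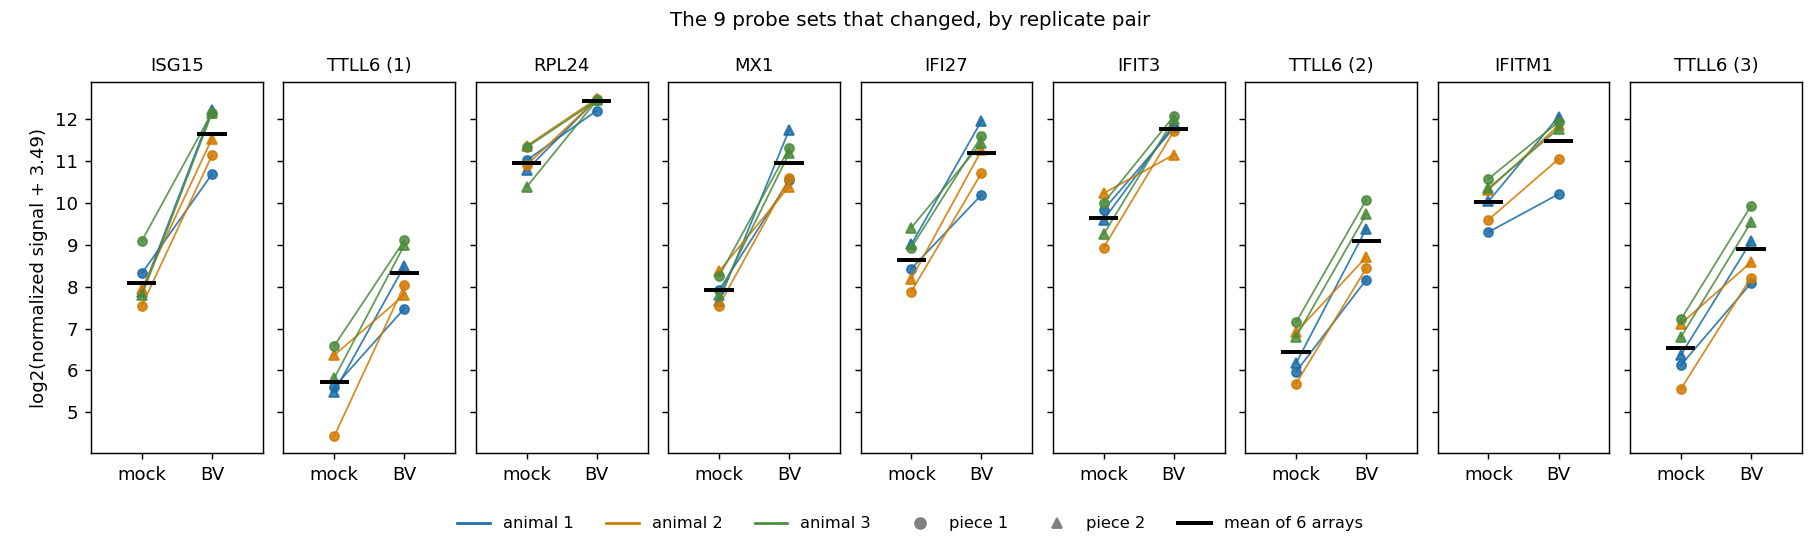
Log2 of the normalized signal plus the pseudocount for each of the 9 probe sets that passed, with mock on the left and BV on the right of each panel, a line for each replicate pair (colour for the animal, symbol for the piece), and a black bar for the mean of 6 arrays. In each panel the BV array lies above its mock partner in 6 of 6 pairs.

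In all, 9 of 31660 probe sets passed in the limma fit, 9 raised and 0 lowered, each in the same direction in 6 of 6 replicate pairs. At an unadjusted p under 0.05 there were 2787, with 1631 higher and 1156 lower, against 1583 by chance. With the 6 replicate pairs as the block on single arrays, 55 probe sets passed, 53 higher and 2 lower, and the 9 were all among them. The 55 hold 34 named genes, 17 of them on the list of interferon-stimulated genes; this fit takes the pieces of an animal as independent. With the piece 1 arrays alone 10 passed, with the piece 2 arrays alone 0 (1781 at an unadjusted p under 0.05), and with a term for piece 38. ISG15 had folds of 3.12 (adjusted p = 0.0466) and 3.82 (adjusted p = 0.116) in these array sets, and MX1 2.98 (adjusted p = 0.0217) and 3.01 (adjusted p = 0.581). The count depended on single animals and arrays: it was 1 without animal 1, 1855 without animal 2 and 79 without animal 3, and 15 without BV replicate 3, 1 without BV replicate 6, 1 without mock replicate 3, 28 without mock replicate 4, 0 without mock replicate 5 (1704 at an unadjusted p under 0.05) and 51 without mock replicate 6. Without normalization, or without the variance trend, 1 passed.

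No gene was called lower. The 5 genes with the smallest p among those with lower values were PAQR6, GMPPA, an enzyme-related subunit of GDP-mannose synthesis, TPM2, a tropomyosin, AFF1 and RAB11B, a small GTPase of recycling endosomes. Their folds were -0.51 ± 0.09, -1.06 ± 0.20, -0.58 ± 0.11, -0.86 ± 0.17 and -1.01 ± 0.20, with adjusted p from 0.353 to 0.397. TPM2 also has probe sets with folds up to 0.37. PAQR6 was called lower in the fit on 6 replicate pairs (adjusted p = 0.0416) and with a term for piece (0.0325), and TPM2 with duplicateCorrelation (0.0296).

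The interferon-stimulated genes rose together as a list. Of its 44 measured members, 40 had higher and 4 lower values in BV tissue, with a median fold of 1.26 (camera adjusted p = 3.67e-29; adjusted p = 0.495 with an estimated correlation). Medians in animals 1, 2 and 3 were 1.31, 0.67 and 2.15. Over all genes tested 4 members passed (ISG15, MX1, IFI27 and IFIT3), while adjusted over the list alone 34 were raised and 1 lowered. The lowered one was TRIM22, a ubiquitin ligase, at -0.68 ± 0.14, of which another probe set had a fold of 1.05. Of 21 members with several probe sets, 7 had probe sets of opposite sign, such as the transcription factor IRF7 with -0.89 for the brightest and 2.07 for the other. TRIM22 and IRF7 were chosen after their values were seen. The median was 1.11 in the piece 1 arrays (adjusted p = 3.98e-26) and 1.54 in the piece 2 arrays (adjusted p = 2.31e-26).

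Genes of antigen presentation were higher too. The MHC class I list, which covers the molecules that show peptides of the cell's own making and the machinery that loads them, rose with a median of 0.65 over 16 members, 15 of them higher (camera adjusted p = 3.29e-09; adjusted p = 0.495 with an estimated correlation). The class I gene MAMU-E had a fold of 2.05 ± 0.37 (adjusted p = 0.344) and the peptide transporter TAP1 1.66 ± 0.37 (adjusted p = 0.441). The MHC class II list, which presents engulfed antigen, rose with a median of 0.97 over 11 members, 10 of them higher (camera adjusted p = 7.5e-06; adjusted p = 0.495 with an estimated correlation). Its members MAMU-DRA and IFI30, a thiol reductase of antigen processing, had folds of 1.28 ± 0.31 (adjusted p = 0.486) and 1.24 ± 0.26 (adjusted p = 0.424). Over all genes 0 members of either list passed, and adjusted over the list alone 11 class I and 4 class II genes were raised. In the piece 1 and piece 2 arrays the class I medians were 0.69 and 0.69, and the class II medians 0.52 and 1.41. The class II median was 0.64 without mock replicate 6 and 0.43 with a covariate of 5 thalamic markers, and 0.62, 0.33 and 1.79 in animals 1, 2 and 3.

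Chemokines, which attract leukocytes, rose as a list with a median of 0.72 over 16 members, 13 of them higher (camera adjusted p = 1.73e-05; adjusted p = 0.495 with an estimated correlation). CXCL10, an attractant of T cells, had a fold of 1.88 ± 0.67 (adjusted p = 0.564), made of 1.32, 0.28 and 4.04 in the 3 animals, and CCL18 had 1.57 ± 0.45 (adjusted p = 0.564). CCL2, which recruits monocytes, had 0.83 ± 0.43 (adjusted p = 0.571). The cytokine and NF-kappaB list rose by a median of only 0.13 over 32 members (camera adjusted p = 0.0218; adjusted p = 0.495 with an estimated correlation), and IL15, IL1RN and IL6 had folds of 1.30 ± 0.38, 0.96 ± 0.41 and 0.33 ± 0.22, none of which passed. This call was lost in the piece 2 arrays (adjusted p = 0.0563), with median centring (0.126), without animal 3 (0.0817), and without BV replicate 4 (0.291) or 5 (0.0651) or mock replicate 1 (0.0908), 3 (0.239) or 6 (0.107). Sensors of nucleic acids and microbial patterns rose with a median of 0.28 over 27 members (camera adjusted p = 0.000944; adjusted p = 0.495 with an estimated correlation). IFIH1, the cytosolic RNA sensor MDA5, and LY96, a partner of TLR4, had folds of 1.97 ± 0.24 (adjusted p = 0.194) and 1.35 ± 0.28 (adjusted p = 0.423), and TLR9, a sensor of unmethylated DNA, had -0.19 ± 0.15 (adjusted p = 0.645). IFIH1, which is on the interferon-stimulated list as well, passed in the fit on 6 replicate pairs (adjusted p = 0.0266), with duplicateCorrelation (0.011) and with a term for piece (0.044). In the piece 1 and piece 2 arrays the medians were 0.41 and 0.76 for chemokines, 0.19 and 0.25 for cytokine genes and 0.21 and 0.46 for sensors. Without mock replicate 6, the array with the highest actin 3'/5' ratio, they were 0.37 for chemokines and 0.15 for sensors, with both calls kept. Chemokines had 0.45 with the thalamic covariate and 0.28 with that of the 5 markers not seen beforehand, where sensors had 0.14. Animal 2 had medians of 0.11 for chemokines and -0.02 for cytokine genes, against 0.92 and 0.10 in animal 1 and 0.80 and 0.30 in animal 3. Adjusted over the list alone, 5 chemokines, 0 cytokine genes and 4 sensors were raised, and over all genes 0 members of the 3 lists passed.

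Among lists of innate immune cells and glial reaction 4 rose, 3 of them with little or no rise in animal 2. Complement had a median of 0.58 over 11 members (camera adjusted p = 1.37e-05; adjusted p = 0.495 with an estimated correlation), with SERPING1, the C1 inhibitor, at 1.37 ± 0.30 (adjusted p = 0.44) and the protease C1S at 1.24 ± 0.29 (adjusted p = 0.468). Neutrophil markers had a median of 0.95 over 8 members (camera adjusted p = 0.000506; adjusted p = 0.495 with an estimated correlation). LCN2, an iron-trapping protein that reactive astrocytes make as well, had 2.07 ± 0.28 for its brightest probe set (adjusted p = 0.236) and -0.25 for the lowest of its 3, and S100A9, a calcium-binding protein of neutrophils and monocytes, 1.34 ± 0.41 (adjusted p = 0.564). LCN2, which is on the reactive astrocyte list too, passed in the fit on 6 replicate pairs (adjusted p = 0.0146). Reactive astrocyte genes had a median of 0.54 over 20 members (camera adjusted p = 7.5e-06; adjusted p = 0.495 with an estimated correlation), among them GBP2, also on the interferon-stimulated list, at 1.53 ± 0.35 (adjusted p = 0.462; lowest of its 3 probe sets -0.03) and GFAP, the astrocyte filament protein, at 0.05 ± 0.07 (adjusted p = 0.796). Microglia and macrophage markers had a median of 0.23 over 22 members (camera adjusted p = 0.0102; adjusted p = 0.651 with an estimated correlation), with LYZ, lysozyme, at 1.47 ± 0.40 (adjusted p = 0.544), MS4A6A at 1.45 ± 0.30 (adjusted p = 0.424) and AIF1, the microglial protein Iba1, at 0.27 ± 0.16 (adjusted p = 0.577). The other probe sets of GFAP and AIF1 had folds of -0.19 and -0.16. The brightest GFAP probe set lay near the top of the signal scale, at mean log2 signals of 12.4 in BV and 12.35 in mock tissue. Its flat fold is therefore weak evidence that GFAP did not rise. Adjusted over the list alone, 6 complement, 4 neutrophil, 6 astrocyte and 0 microglial genes were raised, 1 complement gene was lowered, and over all genes 0 passed. In the piece 1 and piece 2 arrays the medians were 0.58 and 0.79 for complement, 0.44 and 1.49 for neutrophil, 0.57 and 0.56 for reactive astrocyte and 0.21 and 0.33 for microglial genes. In animals 1, 2 and 3 they were 0.66, 0.23 and 1.24 for complement, 1.22, 0.05 and 1.42 for neutrophil, 0.81, -0.01 and 0.80 for reactive astrocyte and 0.36, -0.11 and 0.51 for microglial genes. Without mock replicate 6 the astrocyte median was 0.31 (adjusted p = 0.0198). The neutrophil call was lost with the thalamic covariate (adjusted p = 0.0603) and with that of the 5 markers not seen beforehand (0.102). The microglial call was lost with animal as the block on single arrays (adjusted p = 0.064), with duplicateCorrelation (0.0609), with a term for piece (0.0675), with the covariate of 5 thalamic markers (0.0871), without animal 3 (0.0817), and without BV replicate 2 (0.0547) or 4 (0.32) or mock replicate 1 (0.192), 3 (0.338) or 6 (0.0769).

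Lymphocyte lists gave no call. T and NK cell markers had a median of -0.05 over 16 members (camera adjusted p = 0.896), with GZMB, a protease of cytotoxic granules, at 1.08 ± 0.30 (adjusted p = 0.559) and NKG7 at 0.69 ± 0.22 (adjusted p = 0.564). B and plasma cell markers had a median of -0.08 over 6 members and a camera test that pointed up (adjusted p = 0.96), with JCHAIN at 0.56 ± 0.24 (adjusted p = 0.564) and CD79B at 0.46 ± 0.17 (adjusted p = 0.564). Haemoglobin HBB, a sign of blood in the tissue, had a fold of -0.10 ± 0.15 (adjusted p = 0.793). Its 1 tested probe set was dim, at mean log2 signals of 6.23 in BV and 6.33 in mock tissue. Its folds in single pairs ran from -1.11 to 0.51, so it cannot show that blood content was alike.

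**Figure D2:**
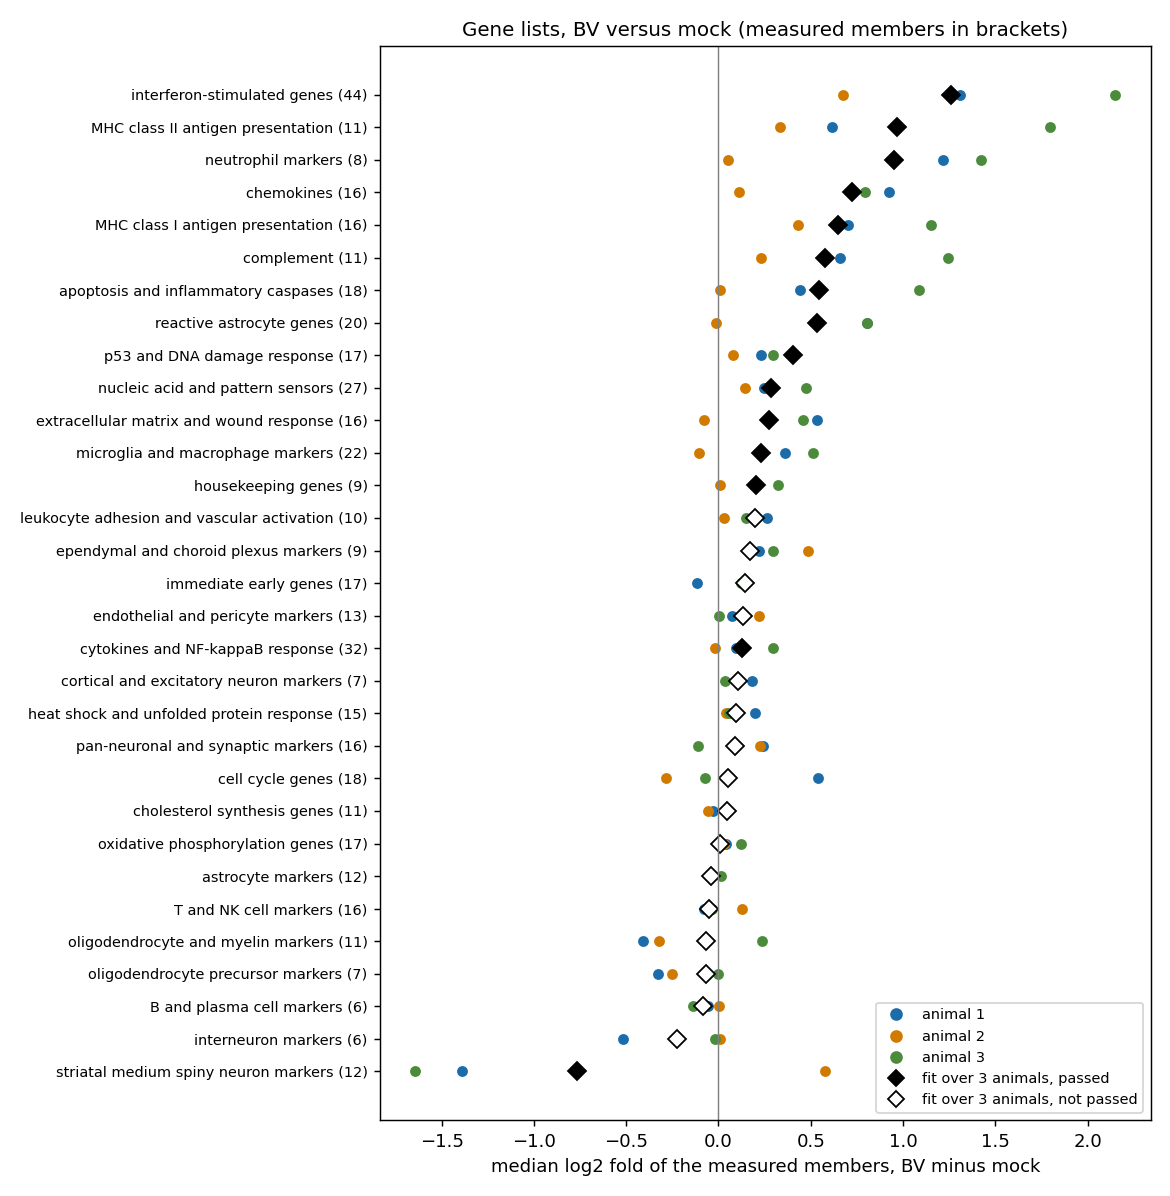
Median log2 fold, BV minus mock, of the measured members of each of the 31 lists (number of members in brackets), for each animal (coloured points) and for the fit over 3 animals (diamonds, filled where the camera test passed at an adjusted p of 0.05). The interferon-stimulated list has the highest median, 1.26, and striatal neuron markers the lowest, -0.77, with animal 2 at 0.58 on the other side of 0.

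The only list called lower was that of markers of medium spiny neurons, the main projection neurons of the striatum. It fell by a median of 0.77 over 12 members, 10 of them lower (camera adjusted p = 0.00616; adjusted p = 0.546 with an estimated correlation), and the animals differed, with medians of -1.39, 0.58 and -1.64. The dopamine receptor DRD2, the receptor GPR6 and PPP1R1B, the striatal phosphoprotein DARPP-32, had folds of -1.17 ± 0.55 (adjusted p = 0.569), -1.16 ± 0.64 (adjusted p = 0.573) and -0.71 ± 0.39 (adjusted p = 0.573), and 0 members passed, over all genes or adjusted over the list alone. The list did not pass in the piece 1 arrays (median -0.27, adjusted p = 0.544) and did in the piece 2 arrays (-1.06, adjusted p = 0.000136). With the thalamic covariate it was called higher instead, at 0.99 (adjusted p = 0.000101). The call was also lost without animal 3 (median -0.25, adjusted p = 0.207), BV replicate 3 (-0.49, 0.149), mock replicate 2 (-0.33, 0.222) or mock replicate 4 (-0.37, 0.329). Fits without a single array mix in the difference between the pieces of that hemisphere. Other neuronal lists did not pass: pan-neuronal and synaptic markers had a median of 0.09 over 16 members (camera adjusted p = 0.15), cortical and excitatory markers 0.10 over 7 (adjusted p = 0.472) and interneuron markers -0.23 over 6 (adjusted p = 0.359). Their members of largest fold were VSNL1 at 0.91 ± 0.24 and the glutamate receptor GRIA1 at -0.82 ± 0.34, NRGN at -0.72 ± 0.51 and MEF2C at 0.36 ± 0.16, and the interneuron peptide NPY at a BV to mock ratio of 0.502 and PVALB, parvalbumin, at 0.73 ± 0.29, with adjusted p from 0.524 to 0.603. Pan-neuronal markers were called higher in the piece 2 arrays (adjusted p = 0.033), without animal 3 (4.72e-05), and without BV replicate 2 (0.0392) or 4 (0.0106) or mock replicate 1 (0.0155) or 3 (0.00273). Cortical markers were called higher with the thalamic covariate (0.021) and with that of the 5 markers (0.017).

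Markers of another brain region were compared as well. Of 16 thalamic markers, a list written after the data had been seen, 8 were measured, with a median fold of 0.94. Their mean was higher in BV tissue in 5 of 6 pairs. That of the striatal markers was lower in 3 of 6. Both moved opposite ways in 4 of 6 pairs. TCF7L2, SHOX2 and NTNG1 had been seen before listing, which favours a rise. The other 5 had a median fold of 0.36 and a higher mean in 4 of 6 pairs. The mean log2 signal of these 8 ran from 6.35 in mock replicate 6 to 9.42 in mock replicate 1, and that of the striatal markers from 6.42 in BV replicate 2 to 9.72 in mock replicate 6. In the pair of replicate 2, the BV array was 1.81 higher in thalamic and 2.85 lower in striatal markers (difference -2.85).

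**Figure D3:**
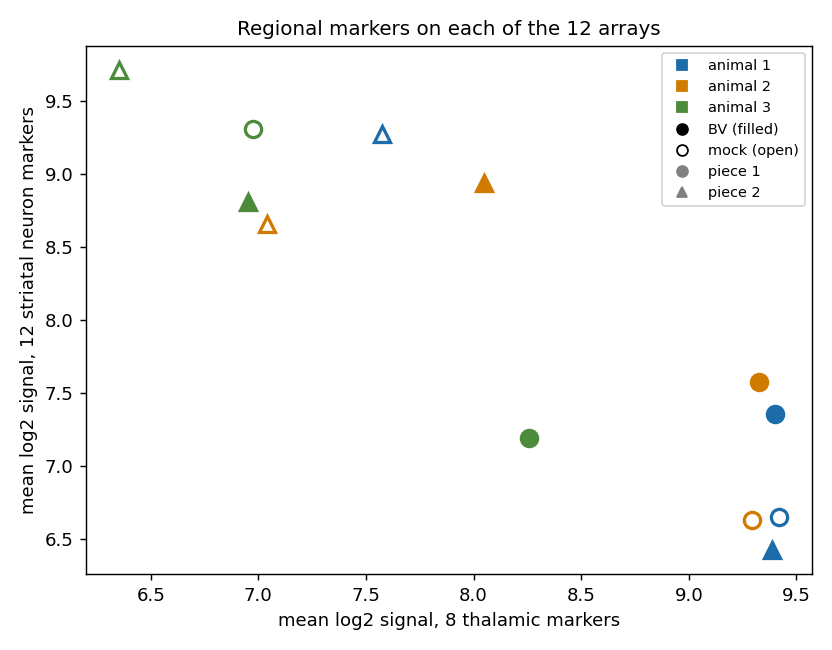
Mean log2 signal of the 12 measured striatal neuron markers against that of the 8 measured thalamic markers on each of the 12 arrays, coloured by animal, filled for BV and open for mock, with circles for piece 1 and triangles for piece 2. Arrays with a thalamic mean above 9 have striatal means between 6.42 and 7.58.

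Lists of cell death and damage rose modestly. Apoptosis and inflammatory caspase genes had a median of 0.55 over 18 members (camera adjusted p = 0.000169; adjusted p = 0.495 with an estimated correlation), with the survival factor BCL2A1 at 2.38 ± 0.60 (adjusted p = 0.508) and MLKL, the effector of necroptosis, at a BV to mock ratio of 2.64 (adjusted p = 0.323). The p53 and DNA damage list had 0.41 over 17 members (camera adjusted p = 0.00115; adjusted p = 0.495 with an estimated correlation), with the death receptor FAS at 0.72 ± 0.27 and the p53 regulator MDM2 at 0.63 ± 0.18 (adjusted p = 0.564 for both). Extracellular matrix and wound genes had 0.27 over 16 members (camera adjusted p = 0.0129; adjusted p = 0.495 with an estimated correlation), among them TGFBI, a matrix protein induced by TGF-beta, at 2.31 ± 0.37 (adjusted p = 0.281; 0.0388 in the fit on 6 replicate pairs) and the protease inhibitor TIMP1 at 1.21 ± 0.32 (adjusted p = 0.532). The lowest of the 3 probe sets of TIMP1 had a fold of 0.06. Adjusted over the list alone 4, 0 and 1 members of the 3 lists were raised, and over all genes 0 passed. In the piece 1 and piece 2 arrays the medians were 0.46 and 0.59 for apoptosis, 0.19 and 0.36 for p53 and 0.27 and 0.36 for matrix genes. Without mock replicate 6 they were 0.34 for apoptosis and 0.19 for p53 genes, and with the covariate of 5 thalamic markers 0.24 and 0.21, with both calls kept. In animal 2 they were 0.01 for apoptosis, 0.08 for p53 and -0.08 for matrix genes. In animals 1 and 3 they were 0.44 and 1.08 for apoptosis, 0.23 and 0.29 for p53 and 0.53 and 0.46 for matrix genes. The p53 median of 0.41 in the fit over 3 animals thus lies above that of each animal. The matrix call was lost in the piece 2 arrays (adjusted p = 0.0734), with a term for piece (0.0771), with median centring (0.0703), without animal 1 (0.0749), and without BV replicate 1 (0.0564) or 4 (0.123) or mock replicate 3 (0.239) or 6 (0.185). The matrix medians were 0.17 without animal 1, 0.28 and 0.096 without BV replicates 1 and 4, and 0.14 and 0.15 without mock replicates 3 and 6.

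Housekeeping genes, held as a control list, had a median of 0.21 over 9 members and passed narrowly (camera adjusted p = 0.0449; adjusted p = 0.495 with an estimated correlation), a call kept under 8 of 33 other settings and lost without any 1 of the animals (adjusted p from 0.0817 to 0.209). SDHA, PPIB, GAPDH and ACTB had folds of 0.30 ± 0.12, 0.26 ± 0.16, 0.16 ± 0.08 and 0.21 ± 0.10, none of which passed. The call was also lost in the piece 1 arrays (adjusted p = 0.606), with no normalization (0.107), without BV replicate 1, 2, 4 or 6, and without any 1 of the 6 mock arrays (adjusted p from 0.0519 to 0.209).

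The other 11 lists did not pass. Astrocyte markers had a median of -0.04 (camera adjusted p = 0.15), with SLC1A2, the main astrocytic glutamate transporter, at a BV to mock ratio of 0.501 (adjusted p = 0.407) and the connexin GJB6 at -0.41 ± 0.14 (adjusted p = 0.564). Myelin markers had -0.07 (adjusted p = 0.324), with UGT8 at -0.35 ± 0.18, MAL at -0.25 ± 0.17 and myelin basic protein MBP at -0.02 ± 0.07, and oligodendrocyte precursor markers -0.07 (adjusted p = 0.28), with BCAN at -0.29 ± 0.15 and NEU4 at -0.23 ± 0.15. MBP also lay near the top of the signal scale, at mean log2 signals of 12.67 in BV and 12.68 in mock tissue. Endothelial and pericyte markers had 0.13 (adjusted p = 0.15), with KCNJ8 at 0.47 ± 0.16 and PECAM1 at 0.36 ± 0.16, and leukocyte adhesion genes 0.20 (adjusted p = 0.15), with PLAU at 1.18 ± 0.41 and the adhesion molecule VCAM1 at 0.80 ± 0.17. Ependymal and choroid plexus markers had 0.17 (adjusted p = 0.108), with FOLR1 at 0.83 ± 0.30, which was 0.04 without BV replicate 1, and KCNJ13 at 0.68 ± 0.20, and heat shock and unfolded protein genes 0.09 (adjusted p = 0.135), with TRIB3 at 1.25 ± 0.32 and XBP1 at 0.53 ± 0.22. Cell cycle genes had 0.05 (adjusted p = 0.621), with MCM3 at 0.83 ± 0.28 and PCNA at 0.68 ± 0.23, and immediate early genes 0.14 (adjusted p = 0.691), with FOS at 1.27 ± 0.41 and KLF6 at 1.26 ± 0.35. The lowest of the 6 probe sets of KLF6 had a fold of 0.23. Cholesterol synthesis genes had a median of 0.05 and a camera test that pointed down (adjusted p = 0.774), with MVD at -0.33 ± 0.16 and SREBF2 at -0.28 ± 0.25. Oxidative phosphorylation genes had 0.01 (adjusted p = 0.691), with UQCRB at 0.28 ± 0.15. Over all genes tested 0 members of these lists passed; adjusted over the list alone 2 astrocyte genes were lowered and 1 adhesion gene was raised. Some lists were called under other settings. Without animal 3 these were the astrocyte (adjusted p = 0.00373), myelin (median -0.39, 2.34e-07), precursor (0.00831) and endothelial (0.0259) lists. Without mock replicate 6 it was the myelin list (median -0.21, adjusted p = 0.00561) and without BV replicate 2 the ependymal list (0.0208). Without mock replicate 4 they were the adhesion (0.0407), heat shock (0.0478) and cell cycle (0.0407) lists. In the piece 2 arrays they were the astrocyte and precursor lists (0.0461 for both), and in the piece 1 arrays the ependymal list (0.0309). With the thalamic covariate they were the ependymal (0.00229), cell cycle (0.017) and immediate early lists (0.0379). With that of the 5 markers they were the ependymal (median 0.67, 0.000176), myelin (median -0.28, 0.00613) and immediate early lists (0.012). Without the filter they were the adhesion (0.0455) and ependymal lists (0.0396), and with means over probe sets the heat shock list (0.0191).

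Over all lists, 15 of 31 passed with the preset correlation, 14 higher and 1 lower, against 0 with an estimated correlation and 0 with fry after adjustment. By fry, which asks whether the genes of a list move 1 way on balance, the lists with an unadjusted p under 0.05 were oxidative phosphorylation (0.0159), ependymal and choroid plexus (0.0172) and interferon-stimulated genes (0.0321).

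The injected animals were also compared with each other, by asking whether the BV effect differed between them. The limma F test of the animal by treatment interaction over the 12 arrays called 0 of 31660 probe sets. At an unadjusted p under 0.05 it had 735, against 1583 by chance, and 1620 with a term for piece, where again 0 passed. Over the tested probe sets, folds of animals 1 and 3 correlated at r = 0.569, those of animals 1 and 2 at 0.139 and those of animals 2 and 3 at 0.013.

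RNA quality was compared through the 3'/5' signal ratios of control probe sets. The log2 ratio of actin was lower in BV tissue by a mean difference of -0.18 ± 0.25 (SD, n = 3 animals; exact sign-flip p = 0.25, two-sided), and that of GAPDH by -0.14 ± 0.13 (SD, n = 3; exact p = 0.5). With 3 animals the smallest p this test can give is 0.25. The actin ratio lay between 1.10 and 1.34 on the piece 1 arrays and between 1.23 and 2.40 on the piece 2 arrays, the highest in mock replicate 6.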

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

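The thalamic covariates, the within-array-set fits, the comparisons of lists between animals, and the tests of scaling, of array set, of neuron loss, of RNA quality and of region for the immune lists were chosen after the results were seen. The tests of region for the interferon and striatal lists use a covariate built after the data were seen, and only their bounds, with the tests of other splits, were written before those fits. The demand that the lower quartile of a list's members stay above the bound was also added after the interferon values were seen. For the immune lists a looser rule, tried after the labels were seen and not kept, asked only that the median and each call hold. By it the first thalamic covariate would argue against region for the 4 lists other than neutrophil markers, and RNA quality would be argued against for neutrophil markers.

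Single arrays stood apart from the other 5 of their group in 8 of 228 groups of values examined, where chance gives about 11.4. The 3'/5' actin ratio of mock replicate 6 was 2.40, with a gap to the next mock array of 0.771 of the range of the group. On the same array the log2 signal of ACTB was 11.81 and the mean of the myelin list 9.95, both below the rest. BV replicate 1 was low in RPL24 at 12.21, and high in FOLR1 at 9.72, against at most 6.26 on the other BV arrays, and in the ependymal and choroid plexus list at 6.61. KCNJ8 was low in BV replicate 6, at 5.61, and the heat shock list was high in mock replicate 4, at 9.08.

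The BV effect on whole lists differed between animals in 22 of 93 camera tests (3 pairs of animals, 31 lists, piece as a term) with the preset correlation and in 0 with an estimated correlation. The spread in these tests is that between the pieces of a hemisphere, so they describe these 3 animals only. Differences are medians over members of the first animal's log2 fold minus the second's. For animals 1 and 2 they were 0.39 for interferon-stimulated genes, 0.72 for chemokines, 0.53 for complement, 0.53 for microglia, 0.98 for reactive astrocytes, -1.86 for striatal neurons, -0.35 for interneurons, 0.69 for matrix genes and 0.87 for cell cycle genes (adjusted p from 9.55e-08 to 0.0331). For animals 1 and 3 they were -0.72 for interferon-stimulated genes, -0.76 for MHC class I, -1.23 for MHC class II, -0.73 for myelin and 0.48 for cell cycle genes (adjusted p from 8.04e-06 to 0.0165). For animals 2 and 3 they were -1.12 for interferon-stimulated genes, -0.80 for MHC class I, -1.33 for MHC class II, -1.01 for complement, -0.61 for microglia, -0.66 for myelin, 2.32 for striatal neurons and -0.80 for apoptosis genes (adjusted p from 9.55e-08 to 0.0338).

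The rise of the interferon-stimulated list was set against 3 technical explanations. Without normalization the list median was 1.27 while the median fold of all genes was -0.0311 (upper quartile 0.14), which argues against scaling as the whole cause. Within array sets the lower list median was 1.11 (lower quartile 0.80), so the rise was not confined to 1 set. Array set was balanced over treatment, so a plain shift between sets cancels between BV and mock. The test within sets could not have shown such a shift as the cause. With the thalamic mean of each array as a covariate in the 6-pair fit the median was 1.09 (lower quartile 0.65), against 1.26 without, and the list still passed (adjusted p = 1.08e-24), but no probe set did (ISG15 3.15, MX1 2.70, IFIT3 2.31 and RPL24 1.46, against 3.56, 3.04, 2.13 and 1.46 without), as the members' median standard error went from 0.24 to 0.36 and the residual degrees of freedom from 5 to 4. With the 5 markers not seen beforehand the median was 0.89 and the list passed (adjusted p = 5.63e-35), so both medians meet the bound written before; the lower quartile, 0.58, fell just under it, so a part of region in the rise cannot be told apart. In pairs 1 and 3, thalamic means differed by -0.02 and 0.03, and the list mean was higher by 0.90 and 1.03. Striatal means were higher by 0.705 and 0.944 in the same pairs, so their pieces were not alike in regional markers. An effect of the virus, and of hemisphere, stay open.

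The fall of striatal neuron markers was weighed likewise. Loss of neurons of all kinds is argued against only as the cause of a fall of this size. The lower quartile of the pan-neuronal members was -0.13, above -0.38, the bound set from the striatal median. A smaller loss was not tested, and region was not held alike in this comparison. A difference in dissected region is a candidate explanation. With the thalamic covariate the striatal median went from -0.77 to 0.99, past 0, and with the 5 markers not seen beforehand to 0.72. The rule written before asked that the median's size fall below that of the same bound, -0.38. Neither covariate met it, as the list was called higher instead (camera adjusted p = 0.000101 and 4.97e-07). The thalamic covariate also raised the variance of the treatment term 2.42-fold. How much of the fall is due to region therefore cannot be told. Of the thalamic markers, RGS16 and TCF7L2 were the brightest in mock tissue, at mean log2 signals of 9.87 and 9.84, with folds of 1.29 and 0.86, while PLCB4 and PRKCD had 0.00 and -0.42; all 8 measured lie above the intensity filter and 0 are on a fixed list. An effect of the virus on these neurons was not tested apart from region and stays open.

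The rise of neutrophil markers was weighed apart from that of complement, MHC class II, microglia and reactive astrocyte genes, as they were seen to behave differently: the thalamic covariate took their median from 0.95 to 0.23 and the list no longer passed (adjusted p = 0.0603), and the 5 markers not seen beforehand took it to 0.23 (adjusted p = 0.102), so region may account for that part. For the 63 genes of the other 4 lists the median was 0.65 with the covariate and 0.56 without, and each list still passed, but the members' lower quartile was 0.13, under the bound; with the 5 unseen markers the median was 0.43 and the microglial list no longer passed (adjusted p = 0.0871), so region cannot be told apart for the 4 together. Complement had 0.68 and 0.54 and reactive astrocyte genes 0.89 and 0.71 with the 2 covariates, with both lists passing, but with the 5 markers the lower quartiles were 0.16 and 0.06. Without mock replicate 6, the array with the high actin ratio, the median over the 4 lists was 0.35 (lower quartile -0.01) and that of neutrophil markers 0.62 (lower quartile 0.37), both quartiles under the bound, so RNA quality cannot be told apart either. Leaving that array out also left piece 1 alone as the mock tissue of animal 3, against both BV pieces. This test therefore mixes in a difference between pieces.

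Chance was checked by other splits of the samples. For the 6 means, 10 splits exist, too few for a share under 0.05; the real one gave 9 probe sets, the highest of the others 1, so 1 split, the real one, had as many. For lists it gave 15, the highest other 18, and 3 splits, the real one included, had as many. The 6 splits that part 1 pair reached 18 lists and 1 probe set. With animal as a block, such a split compares BV with mock within that 1 animal. It carries the real difference of that animal, so its counts are no measure of chance. Of the 3 other splits that part all pairs the highest had 14 lists and 0 probe sets. For the 6 replicate pairs, 1 of 32 splits, the real one, gave 55 probe sets and the highest other 0. These splits take the pieces of an animal as independent, so they cannot exclude chance over 3 animals. For lists 5 of 32 had as many as the real 14, with a highest other of 16, so chance cannot be excluded for the number of lists.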

How the results depend on the processing

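The fits within array sets, with a piece term and with the thalamic covariates were chosen after seeing the data. Against 9 probe sets changed, all raised, the count was 5 without the filter (more probe sets tested), 1 without normalization, 1 without the variance trend and 4 with no replicate block. On single arrays it was 30 with animal as the block and 55 (53 raised, 2 lowered) with replicate number as the replicate block. It was 85 (75 raised, 10 lowered) with duplicateCorrelation, whose consensus correlation of pieces was -0.252, a negative value that makes its p-values smaller. It was 38 (35 raised, 3 lowered) with a piece term, 0 in the piece 2 arrays and 0 with the thalamic covariate or with that of the 5 markers not seen beforehand. Leaving out animals or arrays in turn gave counts from 0 to 1855, raised from 0 to 1164 and lowered from 0 to 691, the highest without animal 2, a fit of 2 animals. The cause of these shifts was not tested, unless stated. All 9 were also called in the replicate block fit and in the duplicateCorrelation fit, and 8 with animal as the block.

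Of 31 lists, 15 passed, against 0 with an estimated correlation and 0 with fry; every other setting gave between 12 and 17. The interferon-stimulated list passed under all 33 of the other settings with the preset correlation, with medians from 0.89 to 1.62. The striatal list reversed with the thalamic covariate, to 0.99 (adjusted p = 0.000101), and with that of the 5 unseen markers, to 0.72 (adjusted p = 4.97e-07); in the other fits with the preset correlation its adjusted p reached at most 0.544. Apart from these 2 reversals, 88 list values lost and 29 gained a call, and 964 kept it or stayed without one; of single named genes 57 lost and 62 gained a call, and 0 reversed. A changed sign with no call in either setting occurred in 58 list and 33 gene values. The interaction gave 0 under each setting run. Under median centring the median of all genes moved to 0.11, so folds there stand relative to that. Probe set signals near the intensity filter limit what dim genes such as IFNB1 can show.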

Other observations

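The fit on 6 replicate pairs, which takes the pieces of one animal as independent, named further genes that the text has not described. Beside interferon-stimulated genes such as IFIT1 (2.60, adjusted p = 0.005), OAS1 (2.57, adjusted p = 0.0266) and IFI44 (2.54, adjusted p = 0.0266), they include TNFSF13B, the B cell survival factor BAFF, at 2.01 (adjusted p = 0.0434), the protease inhibitor SLPI at 1.16 (adjusted p = 0.0485), and STAP1, a signalling adaptor, at 2.04 (adjusted p = 0.0266). DCP2, an mRNA decapping enzyme, had 2.88 (adjusted p = 0.0335) and DHX8, a splicing helicase, 1.94 (adjusted p = 0.0266). Whether the probe sets named DCP2 and DHX8 measure those genes could not be checked. These genes were chosen after their values were seen, and in the fit on 3 animals none of them passed.

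The mean log2 signal of thalamic markers lay between 8.26 and 9.40 in the piece 1 BV arrays and between 6.98 and 9.42 in the piece 1 mock arrays. In the piece 2 arrays it lay between 6.95 and 9.39 for BV and between 6.35 and 7.57 for mock, so the ranges overlap. SHOX2, a thalamic transcription factor seen in the data before the list was written, had a fold of 1.74 that did not pass (adjusted p = 0.101), and was higher in each of the 3 animals.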
